A study of Mus musculus with 19 samples.

How the data were processed

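Whole-heart small RNA of 19 mice in 3 groups was analysed from a pair of tables the authors deposited, 1 comparing isoproterenol with control (595 entries) and 1 comparing isoproterenol plus minocycline with isoproterenol (617 entries). Per the labels, RNA was extracted with the Qiagen miRNeasy Mini kit, library quality was checked on a Bioanalyzer, and reads were cleaned with ACGT101-miR (LC Sciences) of adapter dimers, junk, low-complexity sequence, ribosomal, transfer, small nuclear and small nucleolar RNA families and repeats. The mapper, genome build, miRBase release and normalization method are not given in the sources used here. Removal of those RNA families by the authors means that totals are totals of the listed entries only. These include 41 and 48 predicted microRNAs and, in each table, 26 entries from other parts of mouse microRNA precursors.

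Per the file headers, the authors deposited raw read counts per mature microRNA, length variant or predicted microRNA, and these counts were the input of every test here except 1 alternative that used normalized values. Per the file headers they also deposited normalized read values, a score obtained with 1 factor per library and rounded to whole numbers, and the mean score of each group. No normalized value of isoproterenol library 954 was used here, and the deposited isoproterenol means fit 6 libraries with 954 at a factor of 0.878. The authors' deposited ratio of group means (fold change), its log2 and an unadjusted p-value of a t-type test, per the file headers, were used only for a count: the authors' deposited tables list 173 entries (104 higher, 69 lower) at p below 0.05 for isoproterenol against control and 45 (15 higher, 30 lower) for minocycline plus isoproterenol against isoproterenol.

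Of the 7140 counts of the first table, 98 were 1 to 4, 281 were 5 and 2007 were 0, so a 0 can stand for a few reads. The isoproterenol cells were identical in the 571 entries the tables share, so the tables were joined for the comparison of both drugs with control. Entries in 1 table only (24 and 46) held at most 22 reads and were set to 0 in the other. A set of 76 entries per table shares all counts with another entry, as miR-92a-3p does, and was kept as deposited. Near-identical microRNAs of a family, such as let-7, miR-199 and miR-29 members, can share reads, so their separate values are uncertain. Sequence variants are named by the authors' suffixes and are named here by the mature microRNA.

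The design fixed before the data were examined named a count model for counts. The deposited values are whole-number counts, but they are written with quoted commas between digits and could not be entered as counts in the unit check applied to the tables. The test fixed for normalized values was therefore used on them: limma 3.58.1 in R 4.3.3 on log2(scaled count + 1) with trended empirical Bayes and Benjamini-Hochberg adjustment, called at an adjusted p below 0.05. Count models were not run, a limit of the unit check rather than of the values, which were read as whole numbers. Libraries were scaled by a trimmed mean of log ratios (trims 0.3 and 0.05), and an entry was tested if at least 10 scaled reads were present in as many libraries as the smaller group has. A fold change is on this log2(scaled count + 1) scale, where that of an entry with few reads can be smaller or larger than the ratio of its mean scaled reads. Isoproterenol was compared with control and both drugs with isoproterenol using the libraries of each table, and both drugs with control in 1 fit of all 3 groups.

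The microRNAs named follow a rule made before the data were examined: up to 10 called in each direction with the largest change, up to 4 members of each list, a fixed set of heart and blood microRNAs, and any called in opposite directions. Of the fixed set, no entry under the names miR-142a-5p and miR-486a-5p was tested. The 23 lists (225 entries) were also fixed before the data were examined: heart and striated muscle, hypertrophy, miR-29 and miR-30, fibroblast activation, NF-kB, miR-132 and miR-212, hypoxia, miR-34, let-7, miR-15/16/322, miR-17-92, miR-181, the Dlk1-Dio3 and Sfmbt2 clusters, and markers of fibroblasts, endothelium, smooth muscle, white and red blood cells, neurons, epithelium, liver and skeletal muscle. Lists overlap, since miR-21a, miR-199, miR-214 and miR-132 stand in several. They were tested with camera (preset correlation 0.01) where at least 3 entries were kept, 19 lists per comparison, and again with an estimated correlation.

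Depth was 3166774 to 6548879 reads per library. Reads without molecular identifiers are not independent molecules, so a small count is less precise than counting error alone gives. The procedure was tested on simulated data made from the real means and depths. For isoproterenol against control, with 356 entries tested, a 1.5-fold change was recovered for 81 of 115 changed entries that were tested (70.4%). A 2-fold change was recovered for 112 of 124 (90.3%). For both drugs against isoproterenol the shares were 69.1% (365 tested) and 89.2% (359 tested). For both drugs against control they were 64.7% (355 tested) and 82.6% (356 tested). Changed entries that failed the read filter are left out of these shares. Entries were simulated independently, with as many raised as lowered, so shares for the real data may differ. 2 libraries of a group never agreed within sampling noise (chi-square per degree of freedom 38.4 to 817), so no library was counted as a duplicate. The labels give no replicate numbers that pair mice across groups, and each mouse is 1 replicate.

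Alternatives tried were median-of-ratios scaling, no filter, a mean of at least 100, an exact rank-sum test, pseudocounts of 0.5 and 10, entries summed per mature name, exact mature names only, mouse entries only, robust empirical Bayes, all 3 groups in 1 fit, an unadjusted p and leaving out each library. Scaling to totals, voom weights, identical entries once, the authors' normalized values without library 954, and covariates for miR-6236 and miR-6240 or for red blood cell microRNAs were added after the data had been seen.

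Deposited sequences were matched exactly to microRNA precursors of GENCODE M21 on GRCm38: 509 of 641 matched, 61 of them to more than 1 precursor. Host genes are those annotated on the same strand. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.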

Results

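Small RNA libraries were sequenced from the whole hearts of 19 male wild-type C57BL6/J mice, aged 12 weeks, after 21 days of treatment. Control hearts (n = 6) came from mice with an osmotic minipump that released saline. Isoproterenol hearts (n = 6) came from mice whose pump released 30 mg/kg of isoproterenol per day, a beta-adrenergic agonist that drives cardiac hypertrophy and fibrosis in rodents. The remaining hearts (n = 7) came from mice with the same isoproterenol pump and a daily intraperitoneal dose of 50 mg/kg of minocycline, a tetracycline antibiotic with anti-inflammatory actions. Each library is 1 mouse, named here by its group and the animal number in the labels. Libraries held 4188761 to 5614809 reads of listed entries in controls, 4230053 to 6107141 with isoproterenol and 3166774 to 6548879 with both drugs.

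The muscle microRNA miR-1a-3p alone took 42.8% ± 6.73 of reads in controls (SD, n = 6), 39.4% ± 5.58 with isoproterenol (SD, n = 6) and 37.8% ± 2.38 with both drugs (SD, n = 7). Its share ran from 35.8% to 50.6% among controls, where libraries 940, 944 and 947 held 49.5%, 46.1% and 50.6% and libraries 949, 950 and 956 held 38.0%, 35.8% and 36.7%. The labels name no batch. The tables list mature microRNAs, their length variants and predicted microRNAs as separate entries, and the counts of microRNAs below are counts of such entries. Levels are reads after scaling within 1 comparison, so they are set side by side only within that comparison.

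Isoproterenol raised miR-21a-5p, an abundant microRNA linked to cardiac fibroblast activation, from 27674 ± 1116 to 64009 ± 14440 scaled reads (SD, n = 6 each), a 2.26-fold difference. miR-34c-5p, a p53-induced microRNA, rose 4.46-fold, from 147 ± 30.4 to 695 ± 271 scaled reads (SD, n = 6 each). The muscle microRNA miR-499-5p was 1.78-fold lower, at 20645 ± 2181 against 36795 ± 3959 scaled reads (SD, n = 6 each). miR-150-5p, most abundant in mature lymphocytes, was 1.85-fold lower, at 1912 ± 274 against 3512 ± 240 scaled reads (SD, n = 6 each). Of 31 microRNAs of the imprinted Dlk1-Dio3 cluster on chromosome 12, which is strongly expressed in fetal tissue, 27 rose, and the median log2 fold change of all 31 was 0.98. The comparison asks which cardiac microRNAs differ after 21 days of isoproterenol, with saline hearts as the background.

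**Figure D1:**
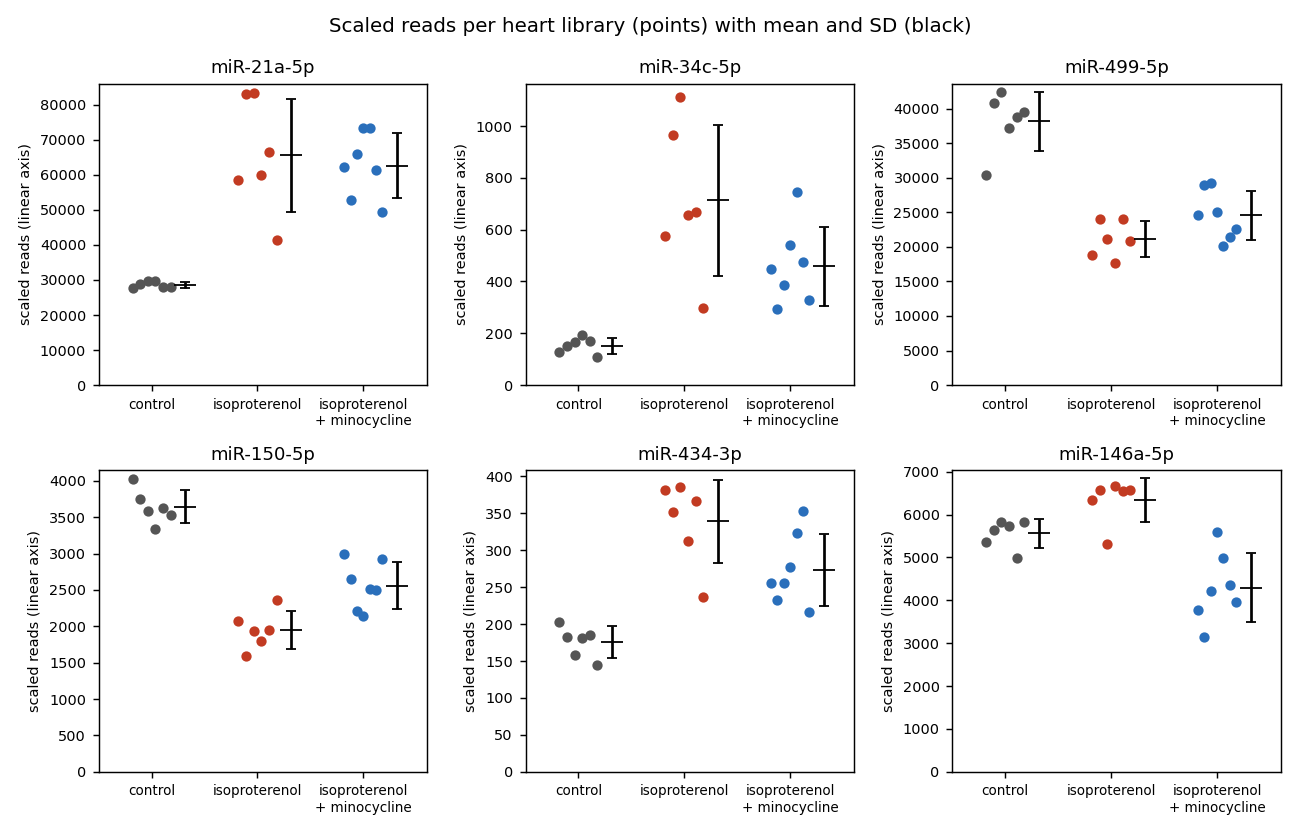
Scaled reads (linear axis, all 19 libraries scaled together) of 6 microRNAs, with 1 point per heart and the mean and SD of each group in black. For miR-21a-5p, miR-34c-5p and miR-434-3p every isoproterenol heart lies above every control heart, for miR-499-5p and miR-150-5p below, and for miR-146a-5p the hearts with both drugs lie mostly below both other groups.

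By limma, the log2 fold changes were 1.18 for miR-21a-5p (SE 0.13, adjusted p = 2.50e-05), 2.16 for miR-34c-5p (SE 0.25, adjusted p = 4.86e-05), -0.83 for miR-499-5p (SE 0.09, adjusted p = 1.87e-05) and -0.89 for miR-150-5p (SE 0.09, adjusted p = 1.87e-05). All 6 isoproterenol hearts lay on the same side of the control mean for each of these. Of 356 microRNAs tested, 75 were higher and 57 lower at an adjusted p below 0.05. Of these, 47 of the higher and 5 of the lower exceeded 1.5-fold. The microRNAs that rose most included several near the detection limit: miR-34b-3p went from 3.29 ± 3.79 to 40.7 ± 13.8 scaled reads and miR-21a-3p, the opposite arm of miR-21a-5p, from 10.1 ± 8.49 to 42.4 ± 13.8 (SD, n = 6 each). Among the lower ones, the epithelial microRNA miR-200c-3p fell from 65.9 ± 19.7 to 22.9 ± 8.72 scaled reads, and miR-185-5p from 7266 ± 280 to 4938 ± 343 (SD, n = 6 each).

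The split between higher and lower moved strongly with scaling to total reads but little with median-of-ratios scaling. Median-of-ratios scaling called 74 higher and 64 lower and kept 131 of the 132 calls. Scaled to total reads, which moved the median log2 fold change of all microRNAs by 0.17, 78 were higher and 5 lower (94.0% of calls higher, against 56.8%). Of the 57 lower microRNAs, 5 kept their call under that scaling, namely miR-499-5p, miR-150-5p, miR-185-5p, miR-200c-3p and the predicted PC-5p-6568_262, and all 57 stayed negative. Of the 75 higher ones, 72 kept theirs. Changes are given relative to the trimmed mean of all microRNAs. With red blood cell microRNAs as a covariate, 49 were higher and 47 lower.

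The miR-21a-5p sequence TAGCTTATCAGACTGATGTTGA lies at 86584120 to 86584141 on chromosome 11 of GRCm38, minus strand, in an exon of Vmp1. miR-34c-5p (AGGCAGTGTAGTTAGCTGATTGC) lies at 51103076 to 51103098 on chromosome 9, minus strand, next to miR-34b-3p at 51103574 to 51103595, with no host gene on that strand for miR-34c-5p. miR-499-5p (TTAAGACTTGCAGTGATGTTT) lies at 155622893 to 155622913 on chromosome 2, plus strand, in an intron of the myosin gene Myh7b. miR-150-5p (TCTCCCAACCCTTGTACCAGTG) lies at 45121762 to 45121783 on chromosome 7, plus strand, in no annotated host gene of that strand. miR-185-5p lies at 18327438 to 18327459 on chromosome 16, minus strand, in an intron of Tango2.

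Of 31 Dlk1-Dio3 microRNAs tested, 27 rose, 0 fell and 4 did not pass (28 rose and 0 fell adjusted over the list alone). The 4 that did not pass also had positive values, from 0.54 to 1.55. miR-434-3p rose by 0.96 (SE 0.12, 332 ± 51.2 against 170 ± 21.7 scaled reads) and miR-409-5p by 1.44 (SE 0.21). Their precursors matched chromosome 12 over 158 kb, from miR-337-5p at 109585818 to miR-410-3p, which ends at 109743784 in an exon of Mirg, both named for their place at the ends. As a list the cluster had a camera adjusted p of 1.42e-11, and adjusted p = 0.100 with an estimated correlation. Taken against the median of the other 325 microRNAs tested in the same library, the mean log2 level of the 31 was higher with isoproterenol than in controls by 1.13 (SE 0.19).

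**Figure D2:**
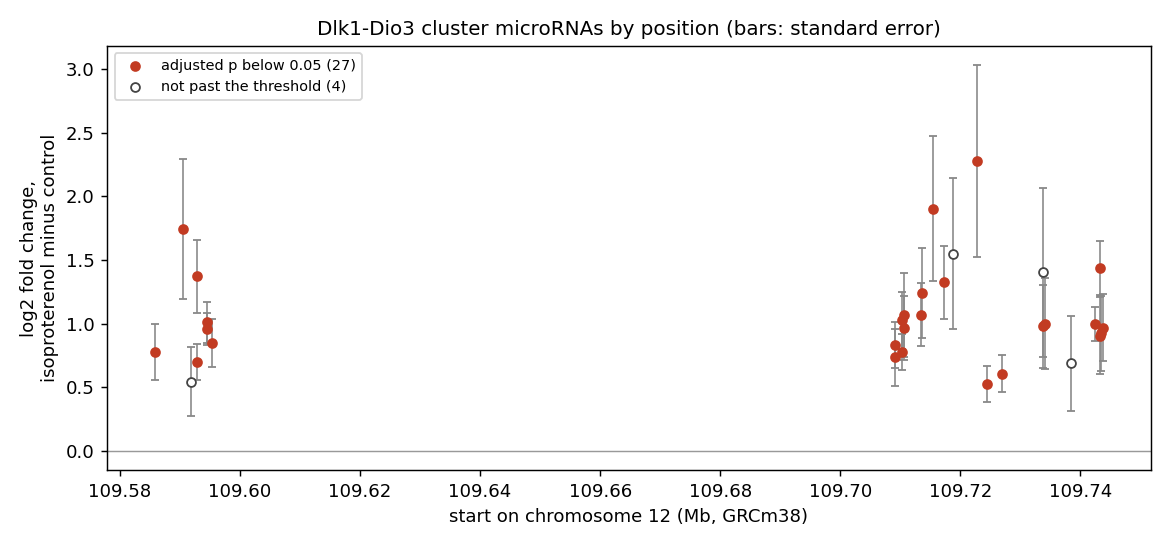
Log2 fold change with its standard error (isoproterenol minus control, n = 6 each) of 31 Dlk1-Dio3 microRNAs against their start on chromosome 12 (Mb, GRCm38), filled where the adjusted p was below 0.05. Points lie above 0 from miR-337-5p to miR-410-3p.

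Of 27 microRNAs widely described as raised in hypertrophied or failing rodent heart, 18 rose, 2 fell and 7 did not pass (20 rose and 2 fell adjusted over the list alone). The risers included miR-199a-5p (0.77), miR-214-3p (0.76), miR-212-5p (1.21) and miR-199b-3p (0.57). The 2 that went against the list were miR-34a-5p (-0.22) and miR-221-3p (-0.30), the latter singled out after its value was seen. For the list the camera adjusted p was 4.96e-06, and adjusted p = 0.0712 with an estimated correlation. miR-208b-3p, from an intron of the fetal myosin gene Myh7 and also in this list, was at 11.7 ± 8.29 against 23.2 ± 15.3 scaled reads (SD, n = 6 each) and did not pass (log2 fold change -0.83, SE 0.94, limma adjusted p = 0.534, or -1.60 without control 940, -0.51 without control 944 and -0.21 without isoproterenol 943).

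All 4 arms of miR-132 and miR-212, a pair of neighbouring microRNAs induced by cAMP and CREB signalling, rose (4 rose and 0 fell adjusted over the list alone). Their log2 fold changes were 1.21 for miR-212-5p, 0.96 for miR-132-5p, 0.70 for miR-212-3p and 0.51 for miR-132-3p (camera adjusted p = 0.00267, and adjusted p = 0.100 with an estimated correlation). miR-132-3p lies at 75173723 to 75173744 on chromosome 11, in an intron of 1700016P03Rik.

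Of 8 arms of muscle microRNAs, 0 rose, 5 fell and 3 did not pass (0 rose and 5 fell adjusted over the list alone). Beside miR-499-5p, miR-133a-3p fell by 0.39 (SE 0.09) and miR-133b-3p by 0.32 (SE 0.08). miR-1a-3p (-0.29, SE 0.21, limma adjusted p = 0.311, or -0.15 without isoproterenol 951 and -0.19 without control 940 or 947) and miR-208a-3p (0.16, SE 0.13, limma adjusted p = 0.351, or 0.09 without control 949), the latter from an intron of the adult myosin gene Myh6, did not pass. Scaled to totals, the calls of miR-133a-3p (-0.22) and miR-133b-3p (-0.15) were lost and that of miR-499-5p was kept. The list's median was -0.32 (-0.15 scaled to totals), with a camera adjusted p of 0.00600, and adjusted p = 0.271 with an estimated correlation. Of 14 arms of the miR-29 and miR-30 families, described as restraining collagen and CTGF, 0 rose, 6 fell and 8 did not pass (0 rose and 8 fell adjusted over the list alone). miR-30e-3p fell by 0.31 (SE 0.07), while miR-29b-3p at -0.09 (SE 0.11, or 0.08 scaled to totals, -0.03 without control 944 and -0.02 without isoproterenol 951) did not pass. The list's median was -0.21 (-0.04 scaled to totals), with a camera adjusted p of 0.00335, and adjusted p = 0.271 with an estimated correlation.

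Of 13 microRNAs described with fibroblast activation, 8 rose, 1 fell and 4 did not pass (10 rose and 1 fell adjusted over the list alone). They included miR-21a-5p, miR-199a-5p (7601 ± 1314 against 4400 ± 417 scaled reads, SD, n = 6 each) and miR-322-5p (0.36), and the 1 that fell was miR-34a-5p. Together they had a camera adjusted p of 0.00267, and adjusted p = 0.132 with an estimated correlation. Of 10 microRNAs mainly of fibroblasts and other mesenchymal cells, 4 rose, 0 fell and 6 did not pass (4 rose and 0 fell adjusted over the list alone). miR-214-3p, from an exon of Dnm3os, rose by 0.76 (SE 0.17). This list had a camera adjusted p of 0.0245, and adjusted p = 0.271 with an estimated correlation.

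Blood and immune microRNAs moved in different directions. Of 6 red blood cell microRNAs, 0 rose, 1 fell and 5 did not pass (0 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0380, and adjusted p = 0.237 with an estimated correlation). miR-486b-5p fell by 0.35, and miR-451a was at -0.69 (SE 0.27, limma adjusted p = 0.0589, below the control mean in 6 of 6 hearts). Of 6 white blood cell microRNAs, 2 rose, 2 fell and 2 did not pass (3 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.996), with a median of 0.19 and a mean of -0.01. miR-223-3p, of neutrophils and macrophages, rose by 0.45 (SE 0.08) while miR-150-5p and miR-155-5p (-0.33, SE 0.08) fell. Of 10 microRNAs tied to NF-kB signalling, 5 rose, 1 fell and 4 did not pass (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0657). miR-146b-5p rose by 0.71 (SE 0.11). miR-146a-5p, which restrains Toll-like receptor signalling, rose by 0.21 (SE 0.07, limma adjusted p = 0.0385, above the control mean in 5 of 6 hearts), from 5362 ± 353 to 6214 ± 597 scaled reads (SD, n = 6 each). The miR-146a-5p call was lost without control 950 (0.17) or isoproterenol 943 (0.19), 951 (0.17) or 958 (0.18), with an adjusted p of up to 0.0899.

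In the remaining lists, the miR-34 family had 3 that rose and 1 that fell of 4 (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0657). The miR-15, miR-16 and miR-322 family had 5 that rose of 17, among them miR-322-5p and miR-351-5p (0.40) (5 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.139). The miR-17-92 family had 5 that fell of 14, among them miR-20a-5p (-0.29) and miR-92a-3p (-0.28), which the table lists as a pair of entries with identical reads (0 rose and 4 fell adjusted over the list alone). The list's camera adjusted p was 0.0249, and adjusted p = 0.271 with an estimated correlation, and its median of -0.14 turned to 0.03 when libraries were scaled to totals. Of 14 let-7 arms, let-7e-5p rose by 0.23 and 13 did not pass (0 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.628). miR-181b-5p fell by 0.41, as 1 of 5 in the miR-181 family (0 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.515). The hypoxia-induced miR-210-3p rose by 0.35 (SE 0.09), the only member of its list tested in this comparison (1 rose and 0 fell adjusted over the list alone).

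Among marker lists of other tissues and cells, those large enough for camera did not pass. miR-126a-5p of endothelium fell by 0.22 and miR-126a-3p was at -0.14 (limma adjusted p = 0.0674), or 0 that rose and 2 that fell of 2 adjusted over the list alone; scaled to totals, miR-126a-3p turned to 0.03. The miR-126a-5p call was lost without control 944 (-0.19), 947 (-0.21) or 956 (-0.17) or isoproterenol 941 (-0.22). Of 4 smooth muscle arms 0 passed, with miR-143-3p at 0.16 (0 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.553). Of 4 epithelial microRNAs, miR-200c-3p fell (0 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.478). Of 3 neuronal microRNAs, miR-128-3p fell by 0.35 (0 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.387). Of 3 liver microRNAs, miR-194-5p (-0.38) and miR-192-5p (-0.31) fell (0 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.105). The 1 tested microRNA of the Sfmbt2 cluster, miR-669c-5p, was at 0.44 and did not pass (0 rose and 0 fell adjusted over the list alone). 0 entries of the skeletal muscle list were tested.

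**Figure D3:**
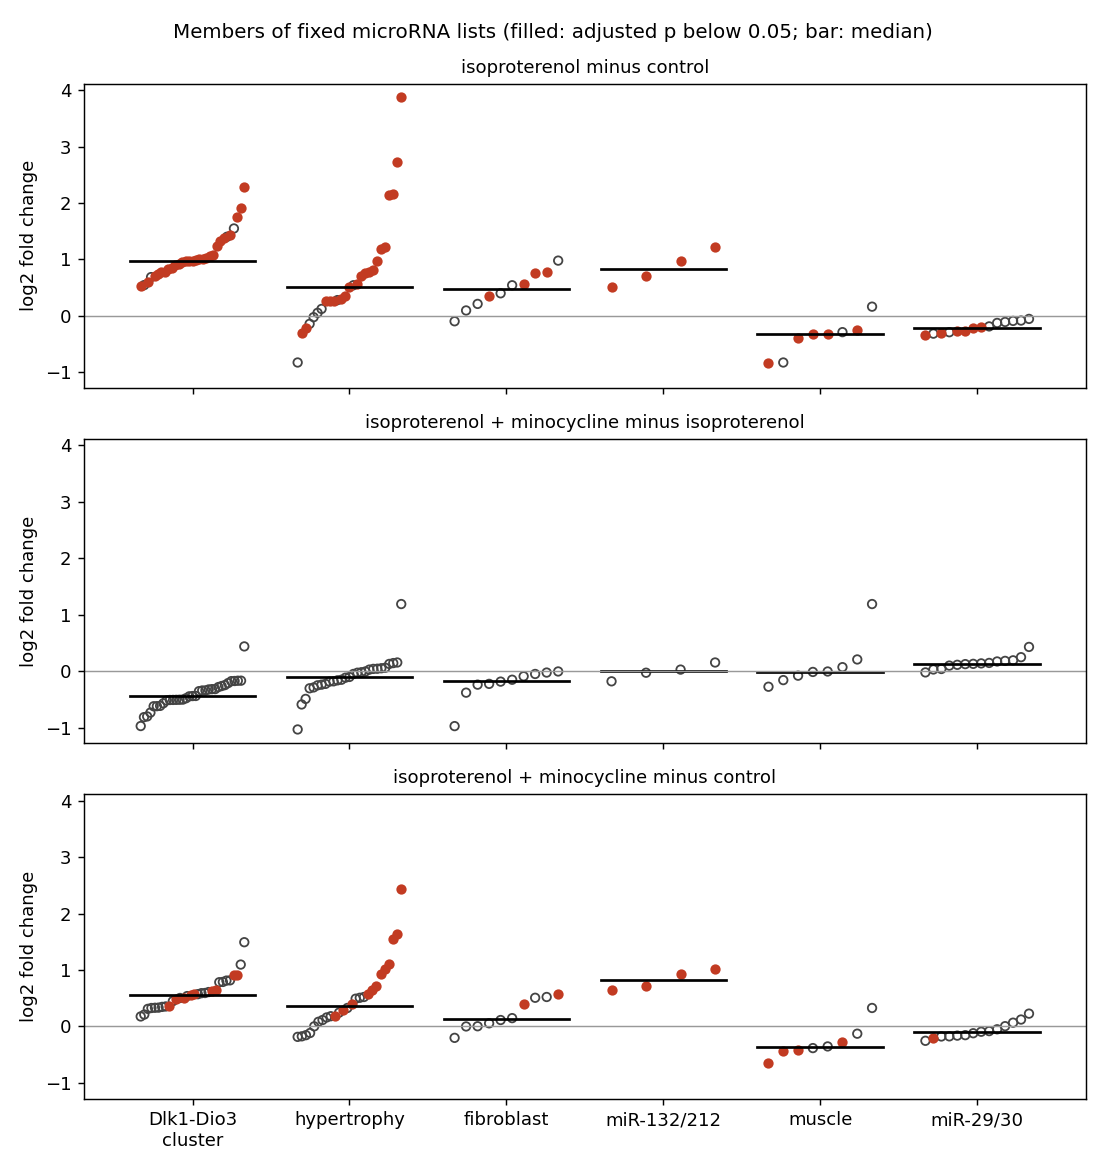
Log2 fold changes of the members of 6 fixed lists in the 3 comparisons, 1 point per microRNA entry, filled where the adjusted p was below 0.05, with the median as a bar. The median of the Dlk1-Dio3 cluster was 0.98, -0.44 and 0.56 from the upper to the lower panel, and that of the miR-29 and miR-30 families -0.21, 0.13 and -0.11, the last of which turned to 0.11 when libraries were scaled to totals.

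With minocycline added to isoproterenol, miR-146a-5p was lower, at 4561 ± 855 scaled reads with both drugs (SD, n = 7) against 6772 ± 587 with isoproterenol (SD, n = 6). All 7 hearts with both drugs lay below the isoproterenol mean, though the groups overlapped. No other microRNA passed the test. The fibroblast-linked miR-21a-5p stood at 66572 ± 9830 with both drugs (SD, n = 7) against 69918 ± 16573 with isoproterenol (SD, n = 6), and miR-499-5p at 26090 ± 3535 against 22582 ± 2981. The comparison asks what minocycline changes in isoproterenol hearts. The labels name no vehicle injection for the hearts without minocycline, so the drug and the daily injection were not separated.

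By limma, miR-146a-5p had a log2 fold change of -0.59 (SE 0.11, adjusted p = 0.0470). Of 363 microRNAs tested, 0 were higher and 1 lower. At an unadjusted p below 0.05 there were 12 higher and 29 lower, where chance alone gives about 18.2 in all. An exact rank-sum test called 0 higher and 0 lower, and limma with voom weights 0 higher and 1 lower. At these group sizes the rank-sum test cannot call 1 microRNA alone after adjustment over 363, so its 0 says little about miR-146a-5p. Scaled to total reads, limma called 0 higher and 0 lower. The miR-146a-5p call was also lost without each of isoproterenol 941, 943, 951, 954 and 958 and of the hearts with both drugs 939, 946, 955 and 957, with values from -0.60 to -0.56 and an adjusted p of up to 0.152. miR-146a-5p (TGAGAACTGAATTCCATGGGTT) lies at 43374435 to 43374456 on chromosome 11, minus strand, in no annotated host gene of that strand. The closely related miR-146b-5p was at -0.15 (SE 0.11, limma adjusted p = 0.614, or -0.09 without isoproterenol 943 and -0.08 without heart 957 of the group with both drugs).

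The next microRNAs by p, each short of the threshold at a limma adjusted p of 0.222, included miR-150-5p (0.39, SE 0.11), miR-335-5p (-0.49, SE 0.14), miR-194-5p (0.19, SE 0.05), miR-215-5p (0.43, SE 0.13) and miR-494-3p (-0.80, SE 0.25). For each, all 7 hearts with both drugs lay on the same side of the isoproterenol mean. miR-34c-5p was at -0.59 (SE 0.27, adjusted p = 0.427) and miR-499-5p at 0.21 (SE 0.10, adjusted p = 0.446). miR-21a-5p was at -0.05 (SE 0.14), miR-1a-3p at -0.08 (SE 0.16), miR-133a-3p at -0.01 (SE 0.11) and miR-155-5p at -0.00 (SE 0.08), and 0 of these passed. Leaving out 1 heart gave values for miR-21a-5p from -0.16 (without isoproterenol 958) to 0.03 (without isoproterenol 943) and for miR-1a-3p from -0.22 (without isoproterenol 951) to -0.01 (without isoproterenol 954). It gave values for miR-133a-3p from -0.07 (without heart 957 of the group with both drugs) to 0.04 (without isoproterenol 941) and for miR-155-5p from -0.04 (without isoproterenol 948) to 0.05 (without isoproterenol 958).

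With minocycline added, 2 lists passed camera with its preset correlation and 0 with an estimated correlation, and 0 members of the 2 passed singly. Of 33 Dlk1-Dio3 microRNAs, 32 were negative, with a median of -0.44 (0 rose and 0 fell adjusted over the list alone). miR-541-5p was at -0.34 and miR-127-3p at -0.32. The cluster's camera adjusted p was 1.05e-10, and adjusted p = 0.551 with an estimated correlation. Of 14 miR-29 and miR-30 arms, 13 were positive, with a median of 0.13 (0 rose and 0 fell adjusted over the list alone). miR-30d-5p was at 0.14 (0.08 without isoproterenol 948) and miR-29b-3p at 0.17 (0.09 without isoproterenol 951 or without heart 957 of the group with both drugs). Here the camera adjusted p was 2.10e-04, and adjusted p = 0.551 with an estimated correlation.

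The other lists did not pass. Camera adjusted p was 0.149 for 10 fibroblast microRNAs (median -0.17, 0 rose and 1 fell adjusted over the list alone), 0.228 for 27 hypertrophy microRNAs (-0.10, 0 and 0) and 0.816 for 10 NF-kB microRNAs (-0.02, or 0.01 scaled to totals, 0 and 1, the latter miR-146a-5p). It was 0.197 for 4 miR-34 microRNAs (-0.54, 0 rose and 1 fell adjusted over the list alone), 0.482 for 6 white blood cell microRNAs (-0.12, 1 and 1) and 0.242 for 3 liver microRNAs (0.04, 1 and 0). The 4 arms of miR-132 and miR-212 had a median of 0.00 and a camera adjusted p of 0.886, and the 13 fibroblast activation microRNAs -0.15 and 0.482. The 8 muscle arms had a median of -0.01 (0.02 scaled to totals), a mean of 0.12 and a camera adjusted p of 0.718, and the 6 red blood cell microRNAs a median of 0.09, a mean of -0.01 and a camera adjusted p of 0.482. In these 4 lists and in the remaining ones, 0 rose and 0 fell adjusted over the list alone.

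Most microRNAs called with isoproterenol had values of the opposite sign when minocycline was added. Of the 132 microRNAs called with isoproterenol, 112 (84.8%) had the opposite sign in that comparison, with a slope of -0.30 of the second log2 fold change on the first. The 132 were called with the same isoproterenol hearts, and no simulation covers this chosen set. Over all 354 microRNAs tested in both, 70.1% had opposite signs, against a mean of 66.7% in 100 simulations of unchanged groups. With the isoproterenol hearts split, a mean of 62.5% had opposite signs in the real data, which is not a value expected by chance. miR-146a-5p was the only microRNA past the threshold in both with opposite signs. Both comparisons use the same 6 isoproterenol hearts, which makes opposite signs common with no effect at all. Across 354 microRNAs, which are not independent replicates, Pearson's r was -0.67, against a mean of -0.48 (lowest -0.81) in those simulations, and the covariance was -0.119 against -0.0430 (lowest -0.111), a difference of -0.0760. With the isoproterenol hearts split into sets of 3, so that each comparison had its own, the covariance averaged -0.0762 over 20 splits (range -0.103 to -0.0116) and the mean r was -0.38. Of the microRNAs called from 3 isoproterenol hearts, a mean of 77.5% (range 65.3 to 88.9) then had the opposite sign, with a mean slope of -0.20 (range -0.33 to 0.04).

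**Figure D4:**
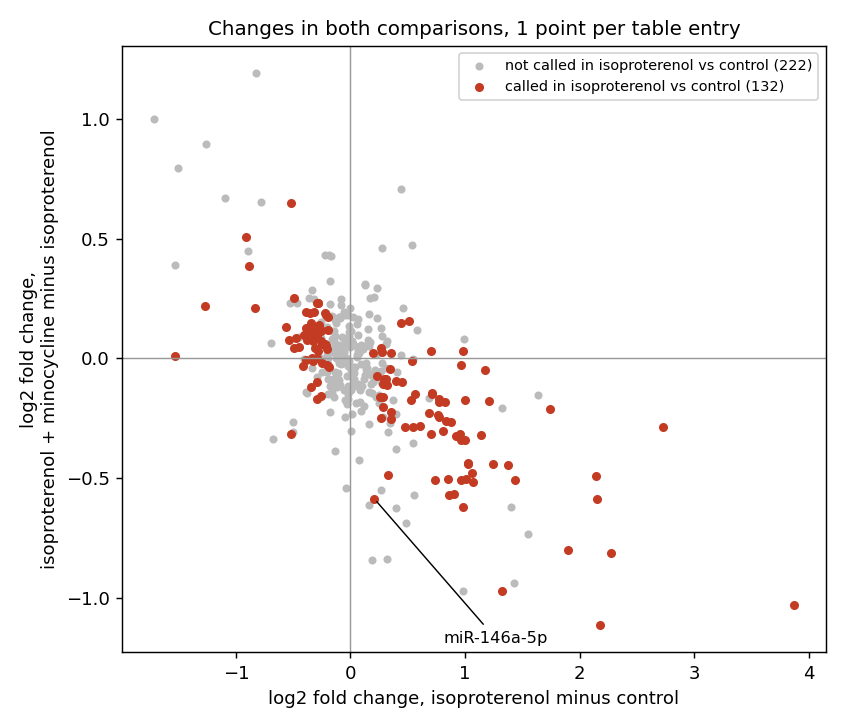
Log2 fold change with minocycline added (vertical, n = 7 against 6) against log2 fold change with isoproterenol (horizontal, n = 6 each) for 354 microRNA entries, with the 132 called in the isoproterenol comparison in red. Of the red points 112 have opposite signs on the 2 axes, which share the isoproterenol hearts.

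In hearts with both drugs, miR-21a-5p was 2.16-fold higher than in controls, at 62639.5 ± 9271 (SD, n = 7) against 28698 ± 841 scaled reads (SD, n = 6), and miR-34c-5p 2.93-fold higher, at 459 ± 152 against 152 ± 30.6. miR-499-5p was 1.56-fold lower, at 24572 ± 3524 against 38184 ± 4233, and miR-150-5p 1.43-fold lower, at 2561 ± 327 against 3642.5 ± 229. miR-146a-5p was 1.31-fold lower than in controls, at 4290 ± 806 against 5560 ± 332, a difference that shrank when libraries were scaled to totals. The comparison asks how far the treated hearts lay from controls.

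By limma, in 1 fit of all 3 groups, the log2 fold changes were 1.11 for miR-21a-5p (SE 0.13, adjusted p = 1.18e-05), 1.55 for miR-34c-5p (SE 0.25), -0.64 for miR-499-5p (SE 0.10) and -0.52 for miR-150-5p (SE 0.09). miR-146a-5p was at -0.39 (SE 0.10, limma adjusted p = 0.00638, or -0.18 scaled to totals) and lay below the control mean in 6 of 7 hearts. Of 355 microRNAs tested, 35 were higher and 34 lower. Median-of-ratios scaling called 40 higher and 32 lower and kept 67 of the 69 calls. Scaled to totals, which moved the median by 0.21, 73 were higher and 3 lower (96.1% of calls higher, against 50.7%). Of the 34 lower ones, 2 kept their call under that scaling and 31 stayed negative, while all 35 higher ones kept theirs. Without control 949 or without heart 942 of the group with both drugs, 54 were higher. The largest called rises were miR-21a-3p (2.44), miR-34b-5p (1.65), miR-34c-5p, miR-21a-5p and miR-212-5p (1.02). The largest called falls were miR-200c-3p (-1.54) and miR-185-3p (-0.85), apart from the predicted PC-5p-6568_262 (-1.07), a call lost in 8 of 19 omissions of a single heart (-0.93 without heart 953 of the group with both drugs).

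All 4 arms of miR-132 and miR-212 rose (4 rose and 0 fell adjusted over the list alone), by a median of 0.82, with a camera adjusted p of 3.21e-05, and adjusted p = 0.0113 with an estimated correlation. Of 26 hypertrophy microRNAs, 12 rose, 0 fell and 14 did not pass (16 rose and 0 fell adjusted over the list alone), among them miR-199a-5p (0.57) and miR-132-3p (0.65). The hypertrophy list had a camera adjusted p of 3.73e-07, and adjusted p = 0.0136 with an estimated correlation. Of 30 Dlk1-Dio3 microRNAs, 9 rose, 0 fell and 21 did not pass (14 rose and 0 fell adjusted over the list alone), with a median of 0.56. miR-434-3p rose by 0.63 (SE 0.13), miR-541-5p by 0.64 (SE 0.12) and miR-409-5p by 0.92 (SE 0.19). Camera gave the cluster an adjusted p of 3.73e-07, and adjusted p = 0.154 with an estimated correlation. Of 13 fibroblast activation microRNAs, 5 rose, 0 fell and 8 did not pass (8 rose and 0 fell adjusted over the list alone; camera adjusted p = 8.54e-04, and adjusted p = 0.137 with an estimated correlation). Of 8 muscle arms, 0 rose, 4 fell and 4 did not pass (0 rose and 5 fell adjusted over the list alone), among them miR-133a-3p (-0.41, SE 0.10). The muscle list's median was -0.37 (-0.15 scaled to totals), with a camera adjusted p of 0.00258, and adjusted p = 0.154 with an estimated correlation.

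Among the lists that did not pass, the NF-kB list had 5 that rose, 2 that fell and 3 that did not pass of 10 (5 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.116). miR-146b-5p rose by 0.55 (SE 0.11) and miR-146a-5p and miR-155-5p (-0.35, SE 0.08) fell. Of 6 white blood cell microRNAs, miR-223-3p rose by 0.34 (SE 0.09) and 3 fell (1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.174). Of 10 fibroblast microRNAs, 2 rose and 8 did not pass (4 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.0880). Of 14 miR-29 and miR-30 arms, miR-30e-3p fell by 0.20 and 13 did not pass (0 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.220). The miR-30e-3p call was lost in 17 of 19 omissions of a single heart (-0.14 without control 947). Scaled to totals, miR-30e-3p was at 0.01 and the list's median turned from -0.11 to 0.11. miR-210-3p rose by 0.29 (SE 0.08).

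The 2 comparisons against controls called many of the same microRNAs. Of 351 tested in both, 33 were higher in both and 28 lower in both, where independent lists of these sizes would share 7.28 and 5.52, a figure that leaves out the shared controls. Simulations of unchanged groups shared a mean of 0, a figure that leaves out the effects. miR-146a-5p was called in opposite directions. Its rise with isoproterenol lost its call in 4 of 12 omissions of a single heart. Its value with both drugs went from -0.39 to -0.18 when libraries were scaled to totals. The same controls enter both comparisons: r was 0.88 against 0.51 in the simulations, and the covariance 0.219 against 0.0442, a difference of 0.175. With the controls split into sets of 3, a mean of 17.2 were higher in both and 9.20 lower in both, and the covariance averaged 0.160.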

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

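The 2 tests on the Dlk1-Dio3 cluster, the covariates behind the red blood cell and miR-6236 values and the scaling to totals were chosen only after the data had been seen.

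In 38 of 360 groups of libraries tested, 1 library lay apart from the rest of its group, with a gap to its nearest neighbour that was a large share of the group's range. For normally distributed values chance alone gives about 1 in 20 such groups, but measures of 1 library are not independent. Some flags below rest on 0 reads, which can stand for a few reads. These are miR-210-5p in isoproterenol 951, miR-431-5p, miR-494-3p and miR-200b-3p in control 947, and miR-219a-5p and miR-208b-3p in control 940. In the group with both drugs they are miR-184-3p in 942 and miR-376c-3p in 953. Isoproterenol library 951 accounts for 9 of the 38 and is the lowest of its group in 8. Its miR-1a-3p share, its share of the 10 most abundant entries and its miR-1a-3p level are overlapping measures. miR-1a-3p took 28.3% of its reads, against 40.3% to 43.3% in the other isoproterenol libraries (gap as a share of range 0.799). The share of the 10 most abundant entries was also lowest there (0.660), as were miR-1a-3p itself (0.692), miR-208a-3p (0.674), miR-126a-5p (0.629), miR-29b-3p (0.629), miR-29c-5p (0.713) and miR-210-5p (0.767), while miR-107-3p was highest (0.647). Library 942 of the group with both drugs accounts for 8: it was highest for miR-125a-5p (0.788), miR-133a-5p (0.746), miR-181b-5p (0.719), let-7a-5p (0.649) and miR-20a-5p (0.573) and lowest for miR-342-3p (0.696), miR-184-3p (0.682) and miR-192-5p (0.6002).

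Library 957 of the group with both drugs held 1029 scaled reads of the predicted PC-5p-2147_1406, against 52.9 to 99.7 in the other hearts of that group (0.788). It was also highest for miR-208a-5p (0.628) and lowest for miR-224-5p (0.583). Isoproterenol library 948 was lowest for miR-146a-5p (0.777), miR-486b-5p (0.734) and miR-208a-5p (0.629) and highest for miR-431-5p (0.635), and isoproterenol 954 was highest for miR-26b-3p (0.628). Control 947 was lowest for miR-431-5p (0.851), miR-494-3p (0.737), miR-200b-3p (0.684) and miR-547-3p (0.671), and control 940 for miR-219a-5p (0.809) and miR-208b-3p (0.691). Control 949 was highest for miR-194-5p (0.636) and miR-486a-3p (0.634), control 956 for miR-669c-5p (0.760), and control 950 was lowest for miR-345-3p (0.690) and miR-30a-3p (0.676). Library 953 of the group with both drugs was highest for miR-219a-5p (0.619) and lowest for miR-376c-3p (0.578).

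With isoproterenol, 132 microRNAs were called against control. Of 100 splits of these libraries, only the real 1 called as many, and the highest of the others called 2. This argues against chance for the count as a whole, not for single microRNAs. The splits cannot show a share below 1 in 100. With the mean of miR-6236 and miR-6240 entries as a covariate, 110 of the 132 stayed called in the same direction, which argues against that axis as the whole cause. With red blood cell microRNAs as a covariate, 88 stayed called and all 132 kept their direction. The share kept, 66.7%, lay exactly at the least share that the rule required. This argues against red blood cells as the whole cause, but only at the limit of that rule. Of the 44 that lost their call, the median size was 0.41 before and 0.41 after while the median SE went from 0.14 to 0.16, so their calls ended through a larger error, and an effect of isoproterenol on them stays a hypothesis.

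Of 31 Dlk1-Dio3 microRNAs, 27 rose with isoproterenol. A scaling factor moves all entries of a library alike, and the mean log2 level of the 31 rose by 1.13 (SE 0.19) against the median of the other 325 tested in the same library, which argues against scaling as the whole cause. The cluster's median exceeded that of the fibroblast microRNAs by 0.51, and the mean gap per library was 0.61 (SE 0.15). A larger share of fibroblasts would move each microRNA by how specific it is to them, which was not measured. The gap therefore does not decide on fibroblasts as a cause, which stay open in part or in whole, since miR-199a-5p and miR-214-3p also rose. An increase within heart cells is another hypothesis, which was not tested.

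Changes with isoproterenol and with minocycline added ran in opposite directions. With the isoproterenol libraries split so that each comparison had its own 3, 0 of 100 regroupings of the residuals gave a mean covariance as low as the observed -0.0762 (lowest -0.0611). The regroupings held no isoproterenol effect, and such an effect widens the spread that this covariance has by chance. They therefore speak only against 3 unchanged groups and do not exclude the shared isoproterenol libraries or chance. Among the 227 entries with a mean of at least 100, the covariance was -0.0319 and 4 of 100 regroupings were as low, with a lowest of -0.0923. A partial return toward control with minocycline is a hypothesis, and an effect of the daily injections stays open because the labels name no vehicle injection.

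For both drugs against isoproterenol, 4 of 100 splits, the real 1 included, called at least 1 microRNA, the real count, and the highest other called 2. The threshold for a call itself limits how often splits without an effect call any microRNA, so the 4 of 100 adds little. Another split called more than the real 1, and the miR-146a-5p call was lost in 9 of 13 omissions of a single heart. Chance therefore stays open for this comparison. For both drugs against control, only the real split of 100 reached 69 calls and the highest other called 27. This argues against chance for the count as a whole, at a resolution of 1 in 100. In that comparison 7 other splits called any microRNA.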

How the results depend on the processing

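Scaling to totals, voom weights, identical entries once, the authors' normalized values and the 2 covariates were chosen only after the data had been seen. For isoproterenol against control, the 75 higher became 44 with a mean of at least 100, 46 with exact mature names and 49 with the red blood cell covariate, and the 57 lower became 36 with exact mature names and 5 scaled to totals. For both drugs against isoproterenol, 12 were higher and 29 lower at an unadjusted p. The 1 lower became 0 with no filter, the rank-sum test, mouse entries only, totals, identical entries once, the authors' normalized values and the miR-6236 and miR-6240 covariate. Of these, the rank-sum test could not have called 1 microRNA alone at these group sizes. For both drugs against control, the 35 higher became 65 unadjusted and 73 scaled to totals, and the 34 lower became 61 unadjusted, 19 with exact mature names and 3 scaled to totals. There miR-30e-3p (0.0147) and miR-194-5p (0.00988) turned positive under totals. With an estimated correlation, lists past the threshold went from 9 to 0, 2 to 0 and 5 to 2 in the 3 comparisons. Scaled to totals, the 1 microRNA past both thresholds with opposite signs became 0, and the covariance of -0.119 became -0.053 with a mean of at least 100 and -0.0627 with a pseudocount of 10. Fewer entries were tested with exact mature names, a mean of at least 100 or mouse entries only; for the other settings the cause was not tested.

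Leaving out 1 library gave 58 to 75 higher and 41 to 60 lower for isoproterenol against control, 0 to 0 higher and 0 to 1 lower for both drugs against isoproterenol, and 31 to 54 higher (54 without control 949 or without 942 of the group with both drugs) and 25 to 36 lower for both drugs against control. The count past both thresholds ran from 0 (without control 950, without isoproterenol 941, 943, 951, 954 or 958, or without 939, 946, 955 or 957 of the group with both drugs) to 1, the covariance from -0.159 to -0.104 and r from -0.73 to -0.61. Of called named microRNAs, 46 of 61, 0 of 1 and 34 of 41 kept their call in every omission. Among the other settings, values for named microRNAs kept direction and side of the threshold in 1169 cases, lost the call in 44, gained it in 6, changed sign without a call in 46 and changed sign with a call in 2. Count models were not run, and the authors' normalized values were not run for both drugs against control. No paired analysis was possible because the labels give no replicate number shared between groups. Depth limits entries near 10 reads, such as miR-34b-3p in controls.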

Other observations

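The microRNAs in this part were chosen after their values were seen, and no explanation was tested for them. All 5 entries of the miR-378 family, which is abundant in muscle, fell with isoproterenol against control by limma, with log2 fold changes from -0.38 to -0.20 (n = 6 each). Scaled to totals, the values ran from -0.21 to -0.03 and the calls of all 5 were lost. All 5 also fell with both drugs against control, from -0.32 to -0.20 (n = 7 against 6). Scaled to totals, these values ran from -0.10 to 0.02, the latter for miR-378d. Of 10 entries of miR-23, miR-24 and miR-27, 6 rose with isoproterenol and 4 did not pass, with a median of 0.27 (0.44 scaled to totals), and 3 rose with both drugs against control.

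miR-511-3p, at 14261051 to 14261072 on chromosome 2 in an intron of the macrophage mannose receptor gene Mrc1, rose by 1.14 (SE 0.17) with isoproterenol and by 0.80 (SE 0.17) with both drugs, each against control, while miR-511-5p did not pass (0.56, SE 0.61, adjusted p = 0.520 with isoproterenol and -0.01, SE 0.65, adjusted p = 0.995 with both drugs, or 0.15 scaled to totals). Both arms of miR-455, from an intron of the collagen gene Col27a1, rose with isoproterenol (0.68 and 0.53) and with both drugs (0.44 and 0.51). miR-224-5p, at 72261084 to 72261105 on chromosome X in an intron of Gabre, was higher by 0.98 with isoproterenol and by 0.99 with both drugs. None of miR-378, miR-511-3p, miR-455 and miR-224-5p passed the limma test when both drugs were compared with isoproterenol, where 0 entries in all were higher and 1 lower at an adjusted p below 0.05, 12 and 29 at an unadjusted p below 0.05, 0 and 0 by the exact rank-sum test and 0 and 1 with voom weights.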
